A study of Mus musculus with 20 samples.

How the data were processed

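RNA was measured in 20 libraries of sorted mouse germinal centre B cells, 5 in each combination of cell type (centroblast, centrocyte) and Myd88 genotype (wild type, heterozygous for L252P). Per the labels' protocols the libraries were made from total RNA with a stranded mRNA kit. The deposited files gave TPM per gene symbol, and per the submitters' processing notes the authors used STAR and the mouse build mm10. Versions, the gene annotation and the tool that counted reads are not given in the sources used here. TPM summed to the same total in each file. Of the gene symbols 20916 matched a current RefSeq symbol and 2236 an older one. TPM keeps no read depth. Among genes under 1 TPM in every library, the ratio of a library's value to that of centroblast control 1 was compared for 214 to 351 genes, of which 105 to 226 shared 1 ratio within 0.003 on the log2 scale. Read as the ratio of what 1 read is worth, it gave a relative depth per unit of gene length between 0.812 and 1.07 of that of centroblast control 1. The absolute depth is unknown, so no counting interval is given. Immunoglobulin genes and mitochondrially encoded genes were not analysed here. Gapdh, which has many processed pseudogenes, lay between 10.6 and 23.9 TPM, so values of genes with near-identical copies are uncertain.

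Samples were grouped by their titles, sort and genotype labels. The test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend and robust) on log2(TPM + 1), two-sided, with 4 group means over the 20 libraries (16 residual degrees of freedom) and a Benjamini-Hochberg adjusted p under 0.05. Genes with at least 1 TPM in at least 5 libraries were tested (11386). The comparisons were genotype in centroblasts, genotype in centrocytes, the difference of these 2, and centrocytes against centroblasts in each genotype. Gene lists (32 lists, 668 of 700 members found) were tested with camera at a preset inter-gene correlation of 0.01 and with an estimated correlation, and 28 lists had the 5 tested members a test needed. The lists of NK cell and dendritic cell markers had 4 and 3. Genes named in the text were Myd88, with Cxcr4, Cd86, Fas and Ptprc as a check of the sort. For each genotype comparison and for the zones in controls they were the 8 largest rises and the 8 largest falls among called genes, with a mean of at least 5 TPM in 1 of the groups and no overlap of the groups of 5. Receptor gene segments, numbered gene models (Gm, Rik, LOC, BC), microRNA, small nucleolar RNA, Y-linked genes and Xist were left out of these. They were also up to 4 called members, by adjusted p, of each list that passed or had at least 3 members called, and, with the same exclusions, the 6 genes with the smallest adjusted p for the difference. Bcl6, Prdm1, Irf4, Myc, Cd40 and Cd83 were given values whether called or not. Some genes that met this rule are not reported here, and counts of list members include them. Replicate numbers were taken to pair libraries only if the deviations from the group means of every same-numbered pair correlated over 0.1. For centroblasts and centrocytes 4 of 5 pairs did so in controls (-0.0168 to 0.259, mean 0.162, other numbers -0.0404) and 4 of 5 in mutants (-2.93e-05 to 0.269, mean 0.175, other numbers -0.0433). The numbers were therefore not used as pairs, although a shared origin of some pairs stays open. Of genes picked afterwards, Beta-s in controls 1 to 5 was 74.3, 20.9, 137, 155 and 260 TPM in centroblasts. In control centrocytes it was 66.2, 37.6, 146, 141 and 259, and in mutants it followed the number less closely. Rpl39l in mutants 1 to 5 was 4.21, 11.8, 1.41, 24.9 and 7.17, and 3.57, 8.83, 1.08, 14.1 and 6.29. If the origin is shared, the zone comparisons and the difference left a real pairing unused. Positions are from GENCODE M21 (GRCm38, the same assembly as mm10). The test, the lists and the rule for named genes were chosen before the data were examined.

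The fit was tested on simulated data with 200 changed genes in each of 3 draws, with noise drawn independently for each gene. With noise given per library, a log2 fold change of 1 was recovered for 92.3% of genes in centroblasts and 91.0% in centrocytes, with 16 and 0.333 false calls per draw, and 74.7% for the difference, with 2.67. A first simulation with noise given per group had 127 false calls per draw in centroblasts, 6.33 in centrocytes, 25.7 for the difference and 106 between the zones in mutants, and the simulation per library was written after that was seen. In both, the pooled spread made more false calls for centroblast mutants, whose libraries varied most, than a fit of the centroblast libraries alone (per library and per group, 0.333 and 21.7). Without centroblast mutant libraries 4 and 5 there were, in the same order, 6 and 430. The noise per group still took its spread from all 5 centroblast mutants, 4 and 5 included. The 430 therefore does not describe the fit of the real libraries without them.

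Alternatives tried were pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM, median-of-ratios scaling, quantile normalization, only the libraries of a contrast, array weights, no trend or robust fit, the replicate number as a block, and leaving out each library. In the genotype fits the block was the bare number, shared by control and mutant libraries. For the zones and the difference it was the number within each genotype. Chosen after seeing the data were a fit without centroblast mutant libraries 4 and 5 and one with a length trend removed in each library. Array weights of these 2 libraries were 0.218 and 0.0651, the lowest of the 20. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.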

Results

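Gene expression was measured by RNA sequencing in germinal centre B cells of mice with and without the L252P allele of Myd88, the adaptor that carries signals from Toll-like receptors and the interleukin-1 receptor family to NF-kB. Both genotypes carried 1 copy of a Cre recombinase under the C gamma 1 locus, which is active in germinal centre B cells. Centroblasts, the dividing cells of the dark zone, had been sorted as B220+ FAS+ GL7+ CXCR4+ CD86- cells, and centrocytes, the light zone cells that are selected by antigen and T cell help, as B220+ FAS+ GL7+ CXCR4- CD86+ cells. The 20 libraries formed 4 groups of 5. They were control centroblasts, Myd88 L252P centroblasts, control centrocytes and Myd88 L252P centrocytes, and Myd88 L252P libraries are called mutant libraries in what follows. Values were TPM, the abundance of transcripts corrected for their length and scaled to the same total in every library, and 11386 genes with at least 1 TPM in at least 5 libraries were tested. Between 12719 and 14092 genes lay above 0 in a library. The labels did not say that the 5 libraries of a group came from separate mice, so p-values measure only the spread between these samples. Values below are means ± SD over n = 5 libraries, and fold changes are on the log2(TPM + 1) scale, which understates changes of low genes.

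Myd88 itself (GRCm38, chromosome 9, 119335934 to 119341411) was transcribed in every group, with 82.5 ± 9.37 TPM in control and 77.2 ± 11.9 in mutant centroblasts, and 74.4 ± 4.76 in control and 88.8 ± 4.07 in mutant centrocytes. Neither genotype difference passed the test (log2 fold change -0.10, adjusted p = 0.48 in centroblasts, where its sign turned with other scalings, and 0.25, adjusted p = 0.328 in centrocytes). In centrocytes all 5 mutant libraries (82.8 to 94.2 TPM) nevertheless lay above all 5 controls (68.1 to 78.9). The missing call there does not show an unchanged level. The allele is a coding change, so a gene-level TPM cannot show it and does not check the labels. Centroblast mutant libraries 4 and 5 differed from the other 18 libraries in composition. Genes with transcripts of at most 778 bases took 42.2% and 47.2% of their TPM, against 34.4% to 38.6% elsewhere. Ribosomal protein genes took 11.3% and 15.2%, against 6.54% to 8.95%, and the 2 libraries held 12895 and 12719 genes above 0, the fewest of the 20.

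**Figure D1:**
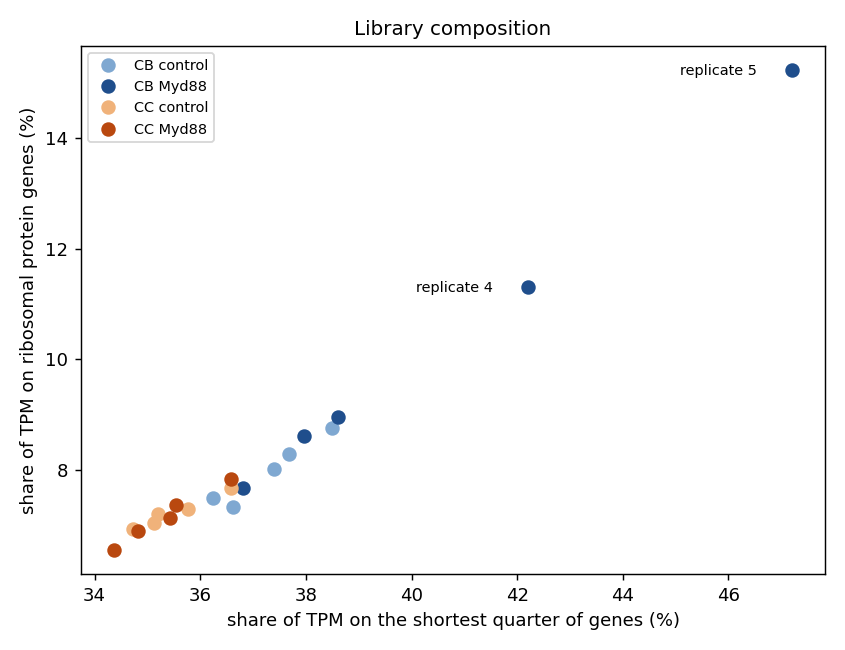
Share of TPM on ribosomal protein genes (vertical axis, %) against the share on genes with transcripts of at most 778 bases (horizontal axis, %), 1 point per library, coloured by group (CB, centroblasts, CC, centrocytes). Centroblast mutant libraries 4 and 5 lie above and to the right of the other 18.

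The comparison of centrocytes with centroblasts in controls shows the zone programmes. Ccr6, a chemokine receptor of memory precursors and resting B cells, was 2.6 ± 0.867 TPM in centroblasts and 56.2 ± 24.1 TPM (log2 fold change 3.94 ± 0.24 SE, adjusted p = 1.97e-10) in centrocytes, the largest rise among the genes named by rule. Next came Fcrl5 (2.98), the cyclin gene Ccnd2 (2.97), the chemokine gene Ccl22 (2.90), Egr3 (2.73), Tlr7 (2.70), Bhlhe40 (2.59) and Cfp (2.46), each with an adjusted p of at most 1.76e-06. The falls were led by Pafah1b3, a subunit of a platelet-activating factor hydrolase, from 758 ± 66.7 to 183 ± 19.1 TPM (log2 fold change -2.05 ± 0.09 SE, adjusted p = 7.30e-13). Ptgr1 (-1.99), Myl4 (-1.96), Tifa (-1.88), Ret (-1.86), Pde2a (-1.84), Lgr5 (-1.80) and the selenoprotein gene Sepp1 (-1.77) also fell, each with an adjusted p of at most 5.61e-07. The sort markers followed the gates and are no finding. Cxcr4 was -0.92 and Cd86 1.17 on the log2 scale, and Fas, positive in both gates, was 0.19 (adjusted p = 0.114). Ptprc, which encodes the protein that carries B220, was 0.95 (adjusted p = 4.55e-05).

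Gene lists fixed before the data were examined moved in blocks. Of 26 light zone genes 24 rose and 0 fell (camera adjusted p = 6.64e-16, adjusted p = 0.0561 with an estimated correlation), among them Cd40, Fcer2a and Slamf1. Of 28 NF-kB target genes 25 rose and 1 fell (camera adjusted p = 2.25e-13, adjusted p = 0.0852 with an estimated correlation), led by Cd40, Ccl22, Ebi3 and Cd83, and 9 tested genes belong to both of these lists. Myc rose from 24.8 ± 4.24 to 81.5 ± 8.31 TPM, with 25 of 30 genes of its ribosome biogenesis list (camera adjusted p = 3.03e-08, adjusted p = 0.105 with an estimated correlation). Antigen presentation genes rose in 14 of 18 cases (camera adjusted p = 2.53e-06, adjusted p = 0.066 with an estimated correlation). Conversely 18 of 28 G2 and M phase genes fell and none rose (camera adjusted p = 1.99e-16, adjusted p = 0.109 with an estimated correlation), with Cdc20 going from 425 ± 55.2 to 193 ± 25.9 TPM. In the dark zone list 8 of 14 fell (camera adjusted p = 1.58e-07, adjusted p = 0.0886 with an estimated correlation), including Neil1 (-1.40), Gcet2 (now Gcsam, -1.58) and Polh (-1.13). Oxidative phosphorylation genes fell in 25 of 32 cases (camera adjusted p = 5.90e-14, adjusted p = 0.0852 with an estimated correlation). Markers of other B cell states and of macrophages moved with the centrocyte gate. The macrophage, monocyte and neutrophil list summed to 92.7 ± 10.3 TPM in centroblasts and 263 ± 80.3 in centrocytes, and 13 of 16 members rose (camera adjusted p = 1.84e-06, adjusted p = 0.254 with an estimated correlation). Naive B cell markers rose in 12 of 13 cases (camera adjusted p = 3.88e-08, adjusted p = 0.109 with an estimated correlation). Without centroblast mutant libraries 4 and 5 the light zone, NF-kB and dark zone lists passed with an estimated correlation (adjusted p = 0.0028, 0.0295 and 0.0295 with an estimated correlation).

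In all, 3498 genes differed between the zones in controls, 2419 higher and 1079 lower in centrocytes, and 6997 differed in mutants, 5561 higher and 1436 lower (limma, adjusted p under 0.05). The median of all genes lay 0.14 above 0 in controls and 0.34 in mutants on the log2 scale. After median-of-ratios scaling the split was 2076 higher and 1978 lower in controls and 3400 higher and 3255 lower in mutants. The genes that led in controls also separated the zones in mutants, with Ccr6 at 4.80 and Pafah1b3 at -2.80. Without centroblast mutant libraries 4 and 5 the counts were 5418 in controls, which these 2 enter only through the pooled spread, and 5773 in mutants, and the median in mutants was 0.17.

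The next question was what the Myd88 allele changed in centrocytes. Mutant centrocytes held more transcripts of Tbx21, Itgax, Itgam and Xlr and fewer of Fos, Cdk5rap1 and Cxcr4. Tbx21, which encodes T-bet, rose from 16.8 ± 8.61 to 45.7 ± 15.2 TPM (log2 fold change 1.46 ± 0.34 SE, adjusted p = 0.0323). Itgax, which encodes CD11c, rose from 1.73 ± 0.721 to 10.2 ± 6.28 TPM (log2 fold change 1.89 ± 0.30 SE, adjusted p = 0.00197), and Itgam, which encodes CD11b, rose from 1.08 ± 0.264 to 4.24 ± 1.39 TPM (log2 fold change 1.30 ± 0.20 SE, adjusted p = 0.00197). The largest rise was that of Xlr, an X-linked lymphocyte-regulated gene, from 0.136 ± 0.206 to 6.71 ± 4.21 TPM (log2 fold change 2.61 ± 0.32 SE, adjusted p = 2.83e-04). Prg2, known for the major basic protein of eosinophils, rose from 2.23 ± 1.14 to 23.7 ± 21.9 TPM (adjusted p = 0.00584). Its mutant mean was 14.7 TPM without centrocyte mutant 2, which held 59.4. Also among the 8 largest rises were the protease inhibitor genes Serpina3g (1.83) and Serpina3f (1.76), Tmem154 (1.60), the glutathione transferase gene Gstt1 (1.57) and the interferon-inducible GTPase gene Tgtp2 (1.46). By the rule that named them, all 5 mutant libraries lay beyond all 5 control libraries for each of the 8. Xlr, Serpina3 and Tgtp2 belong to families of similar copies, so their values depend on how shared reads were counted.

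The largest falls in mutant centrocytes were those of Fos, from 258 ± 32.5 to 122 ± 32.4 TPM (log2 fold change -1.11 ± 0.17 SE, adjusted p = 0.00197), and of Cdk5rap1, which modifies mitochondrial transfer RNA, from 30.9 ± 1.98 to 16.3 ± 0.948 TPM (log2 fold change -0.89 ± 0.15 SE, adjusted p = 0.00291). Cxcr4 fell from 304 ± 17.7 to 167 ± 14.8 TPM (log2 fold change -0.86 ± 0.14 SE, adjusted p = 0.00277), although centrocytes of both genotypes were sorted as CXCR4 negative. Gh (-0.88), Tsc22d3 (-0.85), the phosphatase gene Dusp1 (-0.81), Csrp2 (-0.77) and Rgs2 (-0.64) completed the 8. In all 137 genes were called, 102 higher and 35 lower in mutants, and 60 rose and 1 fell by at least 1 on the log2 scale. The count was 301 with the 10 centrocyte libraries alone and 385 without centroblast mutant libraries 4 and 5. With 1 library left out it was 46 without centrocyte mutant 2, 48 without centrocyte control 4 or centrocyte mutant 3, 63 without centrocyte control 1, 68 without centrocyte mutant 1, 71 without centrocyte control 5, 237 without centroblast mutant 5, and the calls of Serpina3g, Serpina3f, Gstt1, Tgtp2, Csrp2, Rgs2 and Tbx21 were each lost without centrocyte control 4, centrocyte mutant 2 or centrocyte mutant 3 and without at least 1 more library. Calls of Csrp2 and Rgs2 ended after median-of-ratios scaling, those of Serpina3f, Tmem154, Itgam and Tbx21 with a pseudocount of 0.1, those of Gstt1 and Tbx21 with no filter, and those of Prg2 and Csrp2 with the centrocyte libraries alone.

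**Figure D2:**
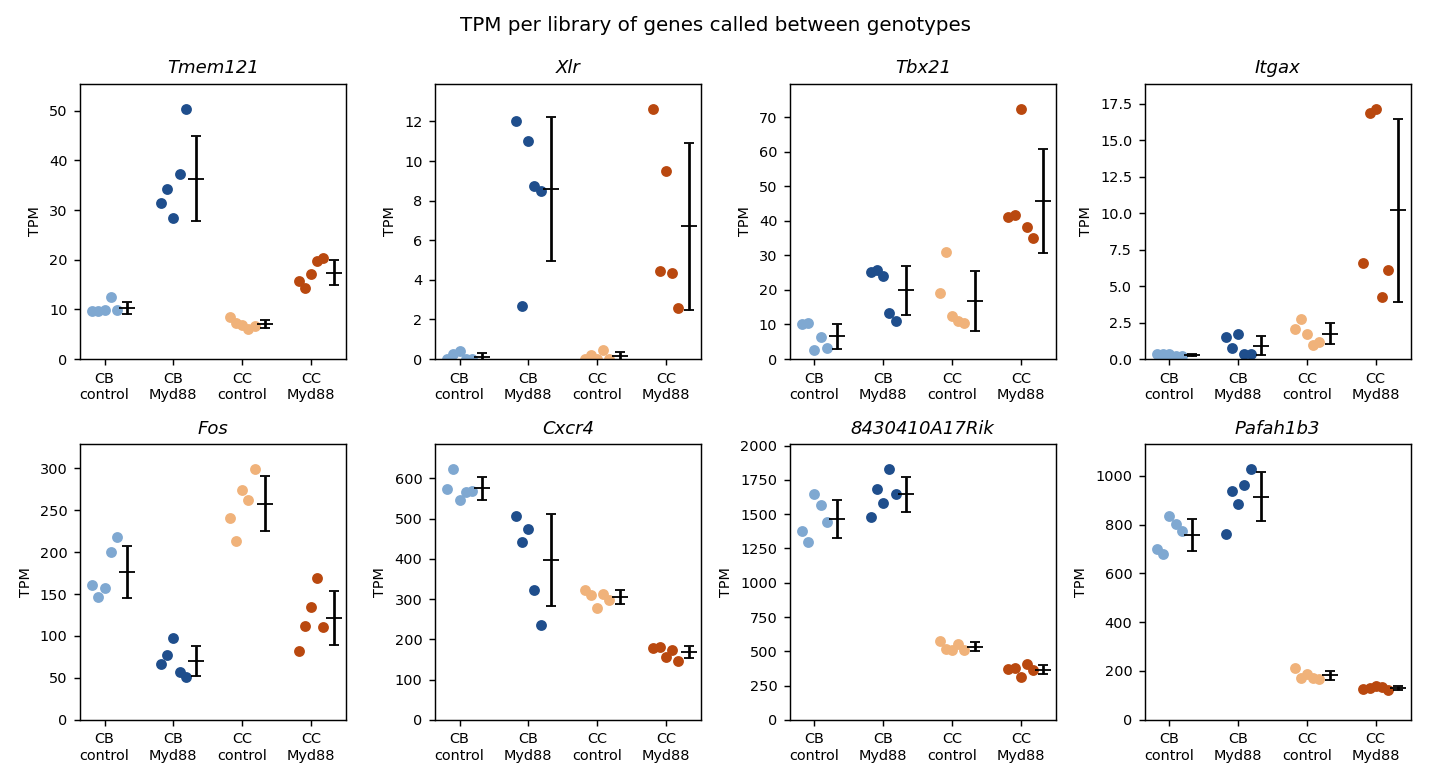
TPM of 8 genes in each of the 20 libraries (points, coloured by group, CB, centroblasts, CC, centrocytes), with the mean and SD of each group of 5 (black dash and bars). Each vertical axis is linear and starts at 0. Xlr was near 0 in controls and averaged 8.6 and 6.71 TPM in mutant centroblasts and centrocytes.

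Among the gene lists, the memory B cell precursor list was higher in mutant centrocytes, with 3 of 24 members rising and none falling, and 12 rising and 1 falling when adjusted over the list alone (camera adjusted p = 5.36e-09, adjusted p = 0.217 with an estimated correlation). Those that rose included Tbx21 and the chemokine receptor gene Ccr6 (from 56.2 ± 24.1 to 114 ± 16.2 TPM, adjusted p = 0.0246). The type I interferon list was higher (2 of 29 rose, 7 adjusted over the list alone, camera adjusted p = 5.72e-09, adjusted p = 0.195 with an estimated correlation), with Isg15 (0.81, adjusted p = 0.0164) and Zbp1 (0.67, adjusted p = 0.0427) called. The MYC and ribosome biogenesis list was higher with no member called and 2 rising adjusted over the list alone (camera adjusted p = 1.85e-10, adjusted p = 0.0946 with an estimated correlation). In the plasma cell list 1 of 28 members rose, Ly6c2, from 2.08 ± 0.827 to 10.5 ± 4.41 TPM, and 3 did so adjusted over the list alone (camera adjusted p = 0.00136, adjusted p = 0.486 with an estimated correlation). Ly6c2 is also expressed by monocytes and other leukocytes. The calls of Ccr6 and Zbp1 were lost without any 1 of at least 7 libraries, and that of Isg15 without centrocyte control 4, control 5 or mutant 3. Both of the former also ended with a pseudocount of 0.1, and that of Zbp1 with no filter, a filter of 5 TPM and no trend or robust fit. In the JAK-STAT3 list 1 of 20 rose (camera adjusted p = 0.0172, adjusted p = 0.723 with an estimated correlation), and the list's call ended with no filter. It was the AP-1 factor gene Batf, from 62.3 ± 5.27 to 104 ± 16.8 TPM (log2 fold change 0.72 ± 0.13 SE, adjusted p = 0.00516). The unfolded protein response list (22 members, camera adjusted p = 0.018, adjusted p = 0.723 with an estimated correlation) and the glycolysis list (18 members, camera adjusted p = 0.00116, adjusted p = 0.142 with an estimated correlation) were higher with no member called.

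Lists that were lower in mutant centrocytes were those of G2 and M phase, the dark zone, germinal centre identity, immediate early and stress genes and cholesterol synthesis. The S phase list, also of division, did not pass, with a median 0.0396 from that of all genes and no member called (camera adjusted p = 0.378, adjusted p = 0.861 with an estimated correlation). The G2 and M phase list lay -0.27 from the median of all genes on the log2 scale, with 1 of 28 members falling and 9 adjusted over the list alone (camera adjusted p = 5.69e-16, adjusted p = 0.15 with an estimated correlation). The one called was Cdc20, from 193 ± 25.9 to 144 ± 11.4 TPM (adjusted p = 0.0323), a call that ended after median-of-ratios scaling and with no trend or robust fit. In the dark zone list 1 of 14 fell, the sort gene Cxcr4, and 5 fell adjusted over the list alone (camera adjusted p = 1.41e-08, adjusted p = 0.0946 with an estimated correlation). In the germinal centre identity list 1 of 26 fell, 8430410A17Rik (now Hmces, a sensor of abasic sites in DNA), from 534 ± 30.5 to 366 ± 32.3 TPM (log2 fold change -0.55 ± 0.08 SE, adjusted p = 0.00141), and 6 fell adjusted over the list alone (camera adjusted p = 7.98e-07, adjusted p = 0.217 with an estimated correlation). Immediate early and stress genes fell in 3 of 17 cases, 6 adjusted over the list alone (camera adjusted p = 4.00e-10, adjusted p = 0.108 with an estimated correlation), and the 3 were Fos, Dusp1 and Ppp1r15a (-0.61). The cholesterol synthesis list was lower with no member called (camera adjusted p = 6.57e-04, adjusted p = 0.368 with an estimated correlation). NF-kB target genes, with 28 tested, had no member called and a median 0.0509 from that of all genes (camera adjusted p = 0.224, adjusted p = 0.817 with an estimated correlation). Without centroblast mutant libraries 4 and 5, 5 of them rose and 0 fell, and the list did not pass (camera adjusted p = 0.0855, adjusted p = 0.584 with an estimated correlation). In that fit the dark zone list and the immediate early and stress list passed with an estimated correlation too (adjusted p = 0.0117 and 0.0117 with an estimated correlation). The calls of Cdc20 and Ppp1r15a were lost without any 1 of at least 7 libraries, each time including centrocyte controls 1 and 4 and mutants 1, 2 and 3. Markers of other cells moved with genotype here as well. Erythroid markers summed to 150.0 ± 88.9 TPM in control and 421 ± 135 in mutant centrocytes (1 of 6 rose, camera adjusted p = 7.98e-07, adjusted p = 0.0946 with an estimated correlation). Marginal zone and B1 markers summed to 799 ± 142 and 1070 ± 136 TPM (1 of 14 rose, Itgam, and 7 adjusted over the list alone, camera adjusted p = 9.20e-06, adjusted p = 0.184 with an estimated correlation).

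In centroblasts the same question gave rises of Xlr, Gstt1, Tmem121 and Tbx21 and falls of Fos, Cdk5rap1, Klf2 and Pdcd1lg2. Xlr rose from 0.124 ± 0.178 to 8.6 ± 3.62 TPM (log2 fold change 2.99 ± 0.32 SE, adjusted p = 2.77e-05). Tmem121, a transmembrane protein gene at chromosome 12, 113185930 to 113189523 (GRCm38), rose from 10.3 ± 1.2 to 36.3 ± 8.54 TPM (log2 fold change 1.70 ± 0.14 SE, adjusted p = 3.91e-07), and was also called in centrocytes (1.19, adjusted p = 2.51e-04). Gstt1 rose by 2.12 on the log2 scale (adjusted p = 0.00544). The other large rises were those of Rpl39l (2.45), the adult beta globin gene Beta-s (2.37), Serpina3g (1.65), Tbx21 (1.54) and Eps8l1 (1.34). Fos fell from 177 ± 31.0 to 70.2 ± 18.4 TPM (log2 fold change -1.34 ± 0.17 SE, adjusted p = 2.25e-04). Cdk5rap1 fell from 37.0 ± 6.2 to 14.7 ± 3.73 TPM (log2 fold change -1.30 ± 0.15 SE, adjusted p = 5.31e-05). The adaptor gene Grap2 (-1.36), the transcription factor gene Klf2 (-1.21), Pdcd1lg2 (-1.16), which encodes a ligand of PD-1, the cytokine receptor subunit gene Csf2rb (-1.12), the calcium channel gene Cacna1i (-1.07) and the atypical chemokine receptor gene Ccbp2 (-1.05) fell as well. The median of all genes lay at -0.16 in this comparison, at -0.0738 without centroblast mutant 5 and at -0.0185 without mutants 4 and 5.

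In all 488 genes were called in centroblasts, 103 higher and 385 lower in mutants, and after median-of-ratios scaling the split was 284 higher and 335 lower. On simulated data the pooled fit made 16 false calls per draw for this comparison with noise given per library and 127 with noise given per group. Where no gene was changed it made 0 and 47.3, in the same order. That noise was independent between genes, while mutant libraries 4 and 5 differed over whole classes of genes. The simulated counts therefore do not give the number of false calls among the 488. With the spread taken from the 10 centroblast libraries alone 24 genes were called, among them Xlr, Tmem121, Gstt1, Eps8l1, Batf, Fos, Cdk5rap1, Dusp1, Klf2, Pdcd1lg2 and Grap2, and without centroblast mutant libraries 4 and 5 the count was 406, 242 higher and 164 lower, of which 199 were among the 488. Calls of Rpl39l, Beta-s, Serpina3g, Tbx21, Csf2rb, Cacna1i and Ccbp2 ended with the centroblast libraries alone, and those of Rpl39l, Beta-s and Csf2rb also without libraries 4 and 5. With array weights those of Beta-s and Csf2rb ended, and that of Csf2rb with no filter. With 1 library left out the count was 147 without centroblast control 2, 168 without centroblast control 5, 185 without centroblast control 4, 204 without centroblast mutant 4, 271 without centroblast control 3, 829 without centroblast mutant 2, 3102 without centroblast mutant 1. Left-out libraries that ended a call were centroblast control 4 and mutant 4 for Rpl39l, control 2 and mutant 5 for Beta-s, control 5 for Serpina3g, and controls 2, 3 and 4 and mutants 4 and 5 for Csf2rb.

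Of 28 lists tested in centroblasts 13 passed with the preset correlation. Immediate early and stress genes fell in 10 of 17 cases and none rose, with the same counts adjusted over the list alone (camera adjusted p = 4.27e-06, adjusted p = 0.382 with an estimated correlation). Dusp1 went from 55.9 ± 4.27 to 27.4 ± 4.87 TPM, Ppp1r15a from 46.8 ± 4.25 to 25.6 ± 5.77 and Zfp36 from 294 ± 50.3 to 178 ± 35.8. Erythroid markers rose in 3 of 6 cases, 4 adjusted over the list alone, with Beta-s and Alas2 (1.87) among those that rose, and summed to 147 ± 91.9 TPM in control and 573 ± 197 in mutant centroblasts (camera adjusted p = 7.87e-07, adjusted p = 0.196 with an estimated correlation). The S phase list (camera adjusted p = 0.00285, adjusted p = 0.749 with an estimated correlation) and the MYC and ribosome biogenesis list (camera adjusted p = 0.00644, adjusted p = 0.749 with an estimated correlation) were higher relative to all genes with no member called. These 4 lists passed under every other setting run for lists except the estimated correlation. The oxidative phosphorylation list passed with 1 of 32 members called, Ndufa1 (0.46, camera adjusted p = 4.93e-09, adjusted p = 0.322 with an estimated correlation), as did the glycolysis list with none (camera adjusted p = 0.00439, adjusted p = 0.322 with an estimated correlation), and both calls ended without libraries 4 and 5, the 2 with the most TPM on short genes. B cell receptor signalling genes fell in 5 of 25 cases, 11 adjusted over the list alone (camera adjusted p = 0.00644, adjusted p = 0.749 with an estimated correlation), with Btk (-0.45), Cd81 (-0.44), Cr2 (-0.91) and Prkcb (-0.84) among them, and the list's call ended after median-of-ratios scaling and with the length trend removed. With 1 centroblast library left out, the call of Btk ended without control 2, that of Cr2 without control 2 or mutant 5, that of Cd81 without control 4 or 5, and that of Prkcb without control 2, 3, 4 or 5 or mutant 4. Calls of Btk, Cd81 and Cr2 ended after median-of-ratios scaling, that of Btk with the length trend removed, that of Cr2 with quantile normalization, that of Prkcb with no filter, and those of Ndufa1, Cr2 and Prkcb without libraries 4 and 5. Of the called list members named here and in the next paragraph, only Dusp1, Ppp1r15a, Klf2 and Batf kept their call with the centroblast libraries alone.

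The remaining lists that passed in centroblasts did so less steadily. Naive B cell markers fell in 3 of 13 cases, 8 adjusted over the list alone (camera adjusted p = 0.0283, adjusted p = 0.749 with an estimated correlation), and Klf2, Cr2 and Fcer2a (-0.60) were the 3. In the MYD88 and TLR pathway list 1 of 26 fell, Irf5 (-0.40, a call that ended after median-of-ratios scaling, with the length trend removed and with the centroblast libraries alone), and 10 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0472, adjusted p = 0.863 with an estimated correlation). The interferon list was higher with Zbp1 called (0.65, camera adjusted p = 0.00702, adjusted p = 0.749 with an estimated correlation). The G2 and M phase list was lower with no member called (camera adjusted p = 0.0427, adjusted p = 0.863 with an estimated correlation). These 4 calls ended without libraries 4 and 5, where the relative median of the MYD88 and TLR pathway list was 0.00521, against -0.18 with all 20. That of naive B cell markers also ended with the replicate number as a block, a filter of 5 TPM and the length trend removed. That of the MYD88 and TLR pathway list ended with a pseudocount of 0.1, a filter of 5 TPM, the centroblast libraries alone and array weights. That of the interferon list ended after median-of-ratios scaling and with array weights. The G2 and M phase call ended under these 2, with a pseudocount of 0.1, a filter of 5 TPM and the length trend removed. The plasma cell list was higher relative to all genes although its 2 called members, Cd93 (-0.86) and Tnfrsf13b (-0.90), fell (camera adjusted p = 0.0283, adjusted p = 0.749 with an estimated correlation), and the macrophage list was higher with none called (camera adjusted p = 0.00407, adjusted p = 0.749 with an estimated correlation), with sums of 92.7 ± 10.3 and 114 ± 31.8 TPM. Both calls ended after median-of-ratios scaling and with the length trend removed, and that of the plasma cell list also with no filter and quantile normalization. Light zone genes did not pass as a list (camera adjusted p = 0.493, adjusted p = 0.911 with an estimated correlation), with Batf rising from 29.2 ± 2.62 to 54.1 ± 12.2 TPM and Egr1 (-0.72), Fcer2a and Cd69 (-0.69) falling. Relative to all genes the memory list had a median and a test below 0 and a mean above 0, and it did not pass (camera adjusted p = 0.874, adjusted p = 0.955 with an estimated correlation). NF-kB targets did not pass either (camera adjusted p = 0.404, adjusted p = 0.911 with an estimated correlation). Without libraries 4 and 5 they did, 4 of 28 rising and 0 falling (camera adjusted p = 0.0309, adjusted p = 0.638 with an estimated correlation). In that fit the JAK-STAT3 list (camera adjusted p = 0.0246, adjusted p = 0.638 with an estimated correlation) and the marginal zone and B1 markers (camera adjusted p = 0.0246, adjusted p = 0.638 with an estimated correlation) were also higher. With 1 centroblast library left out, the call of Zbp1 ended without control 4 or 5, that of Egr1 without control 4, that of Tnfrsf13b without control 2, and that of Fcer2a without control 2, 4 or 5 or mutant 4 or 5. That of Cd69 ended without any 1 of 5 centroblast libraries or 4 centrocyte controls. Calls of Fcer2a and Cd69 also ended after median-of-ratios scaling, with quantile normalization and with no filter, those of Cd69 and Cd93 with the length trend removed, that of Cd69 with no trend or robust fit, and those of Fcer2a, Egr1 and Tnfrsf13b without libraries 4 and 5.

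**Figure D3:**
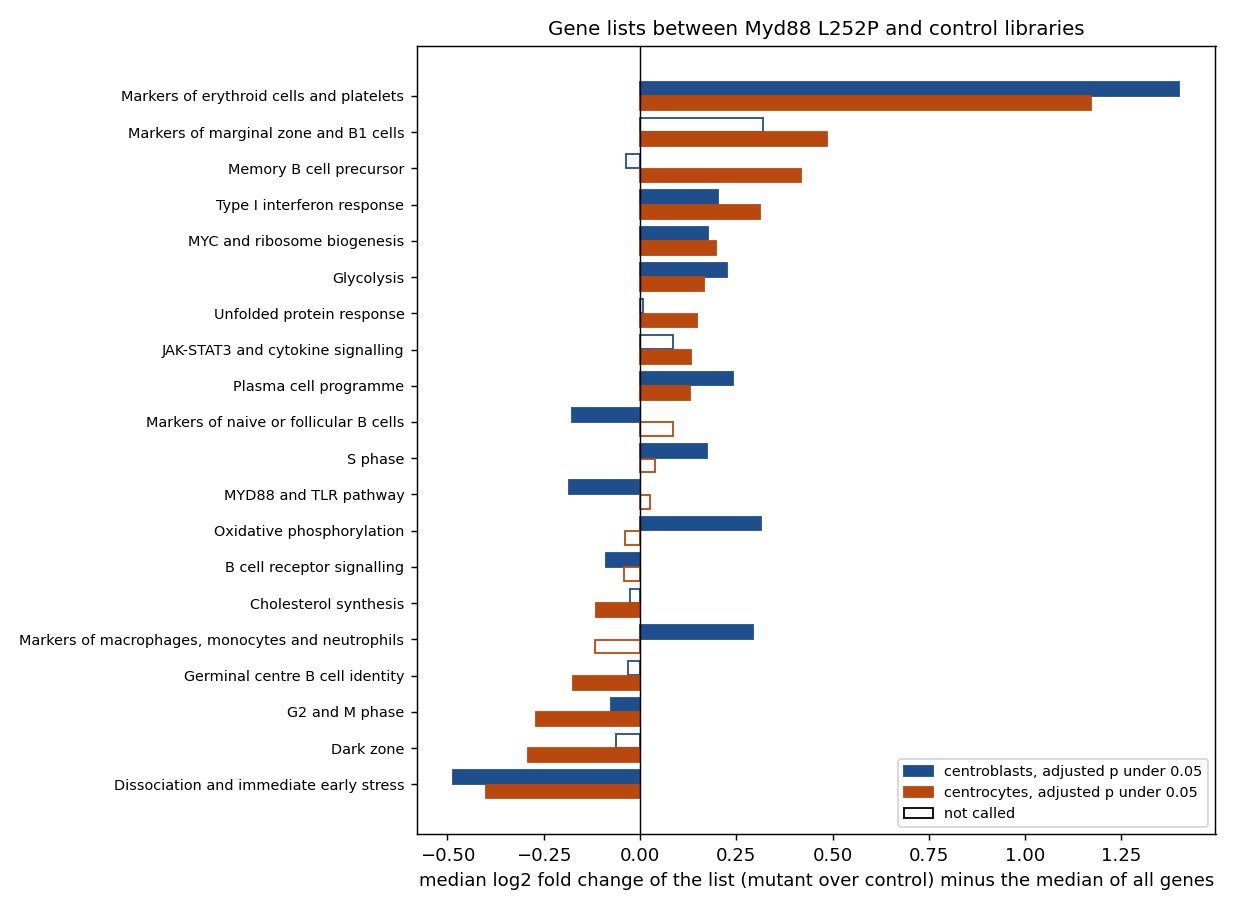
Median log2 fold change (mutant over control) of each gene list minus the median of all genes, in centroblasts and centrocytes, for lists that passed the camera test with a preset correlation in at least 1 cell type. Filled bars mark an adjusted p under 0.05 and open bars lists not called; with an estimated correlation the lowest adjusted p was 0.196 in centroblasts and 0.0946 in centrocytes, so no list passed that way with all 20 libraries.

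Whether the allele acted differently in the 2 cell types was tested as the difference of the genotype effects. With no block for the replicate number it was called for 2 genes. This comparison gave 2.67 and 25.7 false calls per draw on simulated data with noise per library and per group. Those draws held many changed genes, and none without changed genes was run for this comparison. The simulated numbers therefore cannot tell whether the 2 calls are false. 8430410A17Rik (Hmces, chromosome 6, 87913935 to 87936629) averaged 1467 ± 141 TPM in control and 1644 ± 128 in mutant centroblasts (log2 fold change 0.17) and fell in mutant centrocytes (-0.55), a difference of -0.71 (adjusted p = 0.0241). Pafah1b3 (chromosome 7, 25295049 to 25297986) was 0.27 in centroblasts and fell from 183 ± 19.1 to 130.1 ± 7.65 TPM in centrocytes (-0.48), a difference of -0.75 (adjusted p = 0.0241). Both genes were also lower in control centrocytes than in control centroblasts. The next 5 by p, none past the threshold, were Il27 (difference 1.60, adjusted p = 0.0592), Ccbp2 (1.07), Sdc4 (1.25), Cd97 (1.08) and H2afv (-0.55). At an unadjusted p under 0.05 there were 1322 genes. With median-of-ratios scaling no gene was called (1222 at an unadjusted p under 0.05), with no trend or robust fit or the length trend removed likewise none, with array weights 9 and with the replicate number as a block 14, a fit not run on simulated data. With 1 library left out the count was 0 without centroblast control 1, centroblast control 2, centroblast control 5, centroblast mutant 2, centroblast mutant 4, centrocyte control 1, centrocyte mutant 1, centrocyte mutant 2 or centrocyte mutant 5, 1 without centrocyte control 3, 7 without centroblast mutant 1. Prg2, Itgax and Itgam, called in centrocytes and not in centroblasts, had differences of 1.56, 1.39 and 1.12 that did not pass (adjusted p = 0.403, 0.403 and 0.322).

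Genotype calls overlapped between the cell types. Of the 137 genes called in centrocytes and the 488 in centroblasts, 25 were higher and 11 lower in both and 0 moved in opposite directions, where independent lists would share 0.923 and 1.18. The shared genes included Xlr, Tmem121, Gstt1, Serpina3g, Tbx21, Eps8l1, Batf and Zbp1 among the rises and Fos, Cdk5rap1, Cxcr4, Tsc22d3, Dusp1 and Ppp1r15a among the falls. With the centroblast libraries alone the centroblast call of Cxcr4 (-0.59) ended, as did those of Serpina3g, Tbx21 and Zbp1. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.405 with a covariance of 0.0298. In 99 regroupings that kept same-numbered libraries together the median correlation was 0.22, and the highest, 0.511, lay above the observed one. The median covariance was 0.00688 (highest 0.0293), and no gene was shared in any. Splits of the centrocyte libraries, drawn separately, called 40, 8, 2 and 1 genes at most after the real one. Hardly any gene could thus be shared in a regrouping, and that 0 does not test the 36 shared genes. The number shared was 16 with the libraries of each contrast alone and 129 without centroblast mutant libraries 4 and 5. With 1 library left out it was 14 without centrocyte mutant 3, 15 without centrocyte control 4, 16 without centrocyte mutant 2, 18 without centrocyte mutant 1, 19 without centroblast control 5, 22 without centrocyte control 5, 23 without centrocyte control 1, 68 without centroblast mutant 5.

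Regulators of the germinal centre reaction that were given values whether called or not showed no called genotype effect in either cell type. Prdm1, the regulator of plasma cell differentiation, averaged 4.64 ± 1.39 TPM in control and 13.2 ± 7.57 in mutant centrocytes (1.16, adjusted p = 0.157) and 1.48 ± 0.795 and 2.91 ± 1.82 in centroblasts (adjusted p = 0.286). Centrocyte mutants 4 and 5 held 4.92 and 5.83 TPM of it, within the control range of 3.49 to 7.01. The other centrocyte mutants held 15.7 to 22.4. Prg2 (5.93 and 5.52, against 22.1 to 59.4) and Gstt1 (55.9 and 46.7, against 110 to 158) were also lower in centrocyte mutants 4 and 5. Tmem121 went the other way and was highest there (19.7 and 20.2). Bcl6 averaged 339.9 ± 24.8 and 278 ± 31.2 TPM in centrocytes (adjusted p = 0.603) and 322 ± 49.2 and 241 ± 72.7 in centroblasts (adjusted p = 0.0776). The adjusted p in centrocytes was 1.0 for Irf4 (0.19), 0.941 for Myc (0.20), 0.171 for Cd40 (0.21) and 0.921 for Cd83 (-0.18). In centroblasts the log2 fold changes were -0.38 for Irf4, -0.0279 for Myc, 0.19 for Cd40 and -6.96e-04 for Cd83, with adjusted p of at least 0.0829. The signs of 3 of them turned, to 0.15 for Irf4, 0.35 for Myc and 0.19 for Cd83 without centroblast mutant libraries 4 and 5. In centrocytes Prdm1 and Cd40 passed the threshold with array weights and without centroblast mutant libraries 4 and 5, each in the same direction.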

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

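The tests in the paragraphs on libraries 4 and 5, erythroid transcripts and immediate early genes were chosen only after the result was seen. The difference of genotype effects was past its threshold for 8430410A17Rik (-0.71) and Pafah1b3 (-0.75) and for 9 gene lists with the preset correlation. Relative to all genes, the genotype effect in centrocytes minus that in centroblasts had a list median of 0.20 for MYD88 and TLR pathway, -0.19 for G2 and M phase, -0.18 for S phase, -0.33 for Dark zone, -0.0876 for Germinal centre B cell identity, 0.49 for Memory B cell precursor, -0.35 for Oxidative phosphorylation, 0.45 for Markers of naive or follicular B cells and -0.40 for Markers of macrophages, monocytes and neutrophils. With an estimated correlation the lowest adjusted p was 0.704, so none of these lists passed that way with all 20 libraries. Without centroblast mutant libraries 4 and 5, a fit chosen after seeing the data, Dark zone and Germinal centre B cell identity did (adjusted p = 0.0462 and 0.0462 with an estimated correlation). In that fit the medians of the 9 lists were, in the order above, 0.0601, -0.24, -0.11, -0.32, -0.18, 0.39, -0.069, 0.47, -0.62, and 9 of them passed with the preset correlation. With quantile normalization the median of Germinal centre B cell identity turned to 0.0476 and the list did not pass (camera adjusted p = 0.528), nor did S phase and Dark zone, and S phase also did not with no filter.

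In groups of 5, 27 of 496 tested sets of values had 1 library apart from the others by Dixon's ratio, where chance gives about 24.8. The libraries, with their TPM, were centroblast control 2 (Ptprc at 750.0, Tmem154 at 1.02, Tgtp2 at 3.19, Cd93 at 8.04, Cr2 at 219), centrocyte control 5 (Rpl39l at 3.13), centroblast control 4 (Tmem121 at 12.5, Pde2a at 80.3, Ly86 at 339.8, Srm at 63.7), centrocyte mutant 3 (Tbx21 at 72.5, Egr3 at 59.9), centrocyte control 1 (Gh at 34.9), centrocyte control 2 (Ccr6 at 98.0, Cr2 at 440.5, Hhex at 62.7, Asb2 at 10.7). The others were centroblast mutant 1 (Ccl22 at 0.749, Cd93 at 4.02), centrocyte control 3 (Pde2a at 13.8, Jak3 at 50.9), centroblast mutant 5 (Sepp1 at 119), centrocyte mutant 2 (Prkcb at 203), centrocyte mutant 5 (Tlr1 at 104), centrocyte mutant 1 (Mcm5 at 420.0, H2-Oa at 619), centroblast control 5 (Csf1r at 3.8). 5 of them fell in centroblast control 2. This ratio looks for 1 library apart and can miss libraries that lie apart together. It flagged no value of centroblast mutant 4 and only Sepp1 in mutant 5, although these differed in composition. A count near chance thus does not speak for these libraries.

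Centroblast mutant libraries 4 and 5 deviated from their group by an SD over genes of 0.441 and 0.6 on the log2 scale, against 0.226 to 0.337 for the other 18. A trend between short and long genes is not the whole of it, since with that trend removed the lower of the 2 was still 0.421, above the highest other value of 0.328. Fewer reads are argued against by a relative number of reads of 0.989 and 0.906, within the range of the others (0.849 to 1.08). A response common to the mutant centroblasts is argued against by the share of TPM on short genes, where 2 of the other 3 mutant libraries lay within the range of the controls. RNA quality and a difference between samples of the group stay open and were not tested. Prdm1, Prg2 and Gstt1 were also lower in centrocyte mutant libraries 4 and 5 than in the other centrocyte mutants, while Tmem121 was higher. In centroblast mutants 4 and 5 these genes split the same way, with Gstt1 at 27.9 and 36.6 TPM against 86.7 to 126. Deviations of these 2 libraries from their group mean correlated at 0.0659 to 0.269 with those of centrocyte mutants 4 and 5. With the other centrocyte mutants they correlated at -0.302 to 0.0287. Part of the difference was thus seen in both cell types. No fit left out centrocyte mutants 4 and 5 together.

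Erythroid transcripts were higher in mutant libraries of both cell types, with a list median of 1.24 in centroblasts and 1.19 in centrocytes. Scaling is argued against, as the lower of the 2 medians was still 1.13 after median-of-ratios scaling. RNA of red cells or their precursors that was carried along may account for them. The log2 ratio of Alas2 to Beta-s varied over the 20 libraries by 0.377 times the SD of log2 Beta-s, so the 2 genes moved largely together. The ratio itself ran from 0.0214 to 0.0859, where a source with 1 fixed composition would hold it constant. Expression of both genes by the sorted cells could also keep them together, so the ratio cannot tell these apart. The sort for B220 should remove red cells, while Beta-s reached a mean of 537 TPM in mutant centroblasts and Alas2 16.9, of 6 members tested. Expression by the mutant B cells, the biological explanation the genotype gives, was not tested and stays open, as does a difference in the blood or spleen of the mutant mice.

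The immediate early and stress list was lower in mutant libraries, with 10 of 17 members falling in centroblasts and 3 in centrocytes, but did not pass with an estimated correlation in either (adjusted p = 0.382 and 0.108 with an estimated correlation, all 20 libraries). Scaling is argued against by a list median that stayed at -0.41 or lower in both cell types after median-of-ratios scaling. For a weaker handling response of all stress genes, the 3 heat shock members tested were Hspa8, Dnajb1 and Hsph1. Their median relative to all genes was 0.191 in centroblasts and 0.223 in centrocytes, while the other 14 members had -0.547 and -0.436. Hspa1a and Hspa1b, also in the list, were not tested, and Dnajb1 had log2 fold changes of -0.18 and -0.12. The 3 members are therefore too few to decide it. Handling, of all stress genes or of immediate early genes alone, stays open. So does the Myd88 genotype, which the design names and which was not tested apart from handling.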

How the results depend on the processing

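The fits without centroblast mutant libraries 4 and 5 and with a length trend removed, and the counts over other splits, were chosen only after the result was seen. Leaving out immunoglobulin and mitochondrially encoded genes was not run, since it would have moved no tested gene. The 488 centroblast genotype calls became 270 with no filter, 24 with the centroblast libraries alone, 878 with array weights and 147 to 3102 with 1 library left out. The 137 centrocyte genotype calls became 83 with a pseudocount of 0.1, 84 with a filter of 5 TPM, 260 with quantile normalization, 301 with the centrocyte libraries alone, 662 with array weights, 385 without libraries 4 and 5 and 231 with the length trend removed, and 46 to 237 with 1 library left out. The 2 calls of the difference became 4 with a pseudocount of 5, 0 with median-of-ratios scaling (1222 at an unadjusted p under 0.05 by limma), 1 with quantile normalization, 9 with array weights, 0 with no trend or robust fit (1250 unadjusted), 4 without libraries 4 and 5, 0 with the length trend removed (1094 unadjusted) and 0 to 7 with 1 library left out. The control zone calls became 6496 with array weights and 5418 without libraries 4 and 5 and lay at 2637 to 4726 with 1 library left out, and those in mutants at 6297 to 7346. The 36 shared genotype calls became 81 with median-of-ratios scaling, 92 with quantile normalization, 16 with the libraries of each contrast alone, 263 with array weights, 129 without libraries 4 and 5, 98 with the length trend removed and 14 to 68 with 1 library left out. The cause of these moves was not tested.

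Uncalled values in centroblasts changed sign. In the order median-of-ratios scaling, quantile normalization, array weights, without libraries 4 and 5, length trend removed, the log2 fold change of Myd88 was 0.084, 0.0388, 0.0577, 0.0381, 0.10, that of Myc 0.15, 0.17, 0.26, 0.35, 0.16 and that of Cd83 0.19, 0.0414, 0.0802, 0.19, 0.21. Irf4, at -0.38 with all libraries, was 0.0703 with array weights and 0.15 without libraries 4 and 5. With 1 library left out Myc ranged over -0.16 to 0.12 and Cd83 over -0.0826 to 0.12. No called named gene changed direction under any setting run, and no list by its camera test for genotype in a cell type or for the zones in controls, but the relative median of the MYD88 and TLR pathway list in centroblasts went from -0.18 to 0.00521 without libraries 4 and 5. With each reported gene counted only in the comparison it was named for, of 33 called in centroblasts 12 kept the call under every setting and without each library, of 26 in centrocytes 11, and of 69 between the zones in controls 67. With all 20 libraries no list call held with an estimated correlation. Without libraries 4 and 5, 2 lists passed with it for genotype in centrocytes, 2 for the difference, and light zone, NF-kB and dark zone between the zones in controls. Apart from the estimated correlation, 4 of 13 list calls held throughout in centroblasts, 13 of 14 in centrocytes and 15 of 16 between the zones in controls. Lists were not run with libraries left out.

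With the replicate number as a block the counts were 793 in centroblasts, 242 in centrocytes, 14 for the difference, 4203 between the zones in controls, 7322 in mutants and 76 shared. The 793, 242 and 76 came from a block that tied control and mutant libraries of a number, the others from numbers within a genotype. Deviations of same-numbered control and mutant libraries correlated at a mean of -0.00769 in centroblasts and 0.113 in centrocytes. That tie has no basis in centroblasts, and the 2 kinds of count are not comparable. Chance splits of the libraries were counted in 100 draws each. The real centrocyte genotype split called 137 genes and 1 of 100 called as many, the highest other calling 40. In centroblasts 3 of 100 called as many as the real 488, the highest other calling 1244, with mutant libraries 4 and 5 on 1 side. A split that calls over 2 times the real count points to a structure of the samples. For the difference 1 of 100 called as many as 2 (highest other 1), for the zones in controls 1 (real 3498, highest other 1951) and in mutants 1 (real 6997, highest other 4849). The share was under 0.05 for the centrocyte genotype count and the counts between the zones, at 1 of 100, the lowest these draws can give. This argues against a chance division of the libraries there, if they are separate samples. The splits between the zones did not keep same-numbered libraries together. The shares for centroblasts and for the difference were also under 0.05, but in centroblasts 2 splits that mixed genotypes called more genes than the real one. For the difference, the 2.67 and 25.7 false calls per draw, with noise per library and per group, came from simulated data that held many changed genes. They cannot tell whether its 2 calls with no block are false. Absolute depth is unknown, so its limits are not given.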

Other observations

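The test of genes near Myd88 was chosen only after the result was seen. Some genes chosen after their values were seen, of which only Sepp1 had been named by rule, for the zones, were called in both cell types. Trp73, a p53 family member, rose with the allele (1.38 in centroblasts, 1.22 in centrocytes), as did Gstt2 (1.13 and 0.81), the genomic neighbour of Gstt1, S100a10 (0.79 and 1.21) and the actin-capping protein gene Capg (0.72 and 0.86). Aldh2 (-0.65 and -0.56), the linker histone gene Hist1h1c (-0.61 and -0.58) and Sepp1 (-0.59 and -0.54) fell in both. The largest adjusted p of these 7 genes in either cell type was 0.0433, that of Trp73 in centrocytes. With the centroblast libraries alone the centroblast calls of S100a10, Capg and Hist1h1c ended.

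Il2rb and Cxcl10 were likewise chosen after their values were seen. Il2rb, the receptor subunit shared by interleukin-2 and interleukin-15, was in the NK cell marker list, which had too few tested members for a list test. It averaged 8.63 ± 1.38 TPM in control and 23.2 ± 9.7 in mutant centrocytes (1.24, adjusted p = 0.016) and 2.72 ± 0.459 and 4.19 ± 1.91 in centroblasts (adjusted p = 0.27). The summed NK list went from 17.9 ± 6.55 to 37.0 ± 15.7 TPM in centrocytes, and that of dendritic cell markers, also with too few members for a test, from 72.3 ± 11.9 to 98.6 ± 11.2. The NK sum includes Il2rb itself, and the dendritic cell sum includes Itgax and Bst2. Bst2, the highest of that list in mutant centrocytes (46.4 TPM), is also in the interferon list. The sums are therefore not separate evidence of NK or dendritic cell RNA. The interferon-inducible chemokine gene Cxcl10 was 2.42 in centrocytes (adjusted p = 0.0126) and 0.59 in centroblasts (adjusted p = 0.388), and the difference of these effects did not pass (adjusted p = 0.403).

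Tsc22d3 and Dusp1, both induced by glucocorticoids, were lower in mutants, so a lower level of glucocorticoid-induced genes as a class was a candidate explanation. A list of other such genes, written before its values were seen, had 8 members tested, 0 of which were called in either cell type, and the larger of its 2 adjusted camera p was 0.704, which argues against it. Sequence carried along with the allele around Myd88 was a candidate explanation for called genes nearby, but of 166 tested genes within 15 Mb 3 were called in centroblasts and 0 in centrocytes. The larger of the 2 one-sided Fisher exact p was 1.0, so no excess was found.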
